A study of Mus musculus with 8 samples.

How the data were processed

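Total RNA of cultured mouse muscle stem cells was profiled in 8 libraries, 4 with Cre adenovirus and 4 with GFP adenovirus, each group from 4 mice per the series' design text. The cells had been sorted by flow cytometry from mice with loxP-flanked Chd4, expanded briefly, infected and snap frozen, and libraries were made with a stranded protocol, per the labels' protocols. STAR 2.5.3a, featureCounts 1.5.3 from Subread, and DESeq are named with the builds mm10 and GRCm38, per the submitters' processing notes. Their order, settings and filters, the annotation release and whether counting used strand are not given in the sources used here.

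A single table held 20976 genes with coordinates and whole numbers for each library. The deposited values are treated as a score, since they are not raw reads: the totals of the libraries lay between 27897860 and 28876348, median-ratio factors lay between 1.000 and 1.011, and low whole numbers were missing or doubled at regular steps. Such gaps arise when counts are divided by a size factor and rounded. The multiplier of each library was estimated from the gaps up to a value of 300 and lay between 0.741 and 1.20, and 0 genes sat at a whole number predicted to be empty. On simulated data with 8 libraries the estimate was off by at most 1.75e-05. The estimated original depth was 28.5 ± 1.72 M reads in Cre and 28.1 ± 6.73 M reads in GFP (SD, n = 4 each). At such depth counting error is small for well expressed genes, and the spread between mice sets the precision, while genes near 20 reads carry larger counting error. Reads are not independent molecules, and rounding adds an error of less than 1 read. The 10 most abundant genes took 5.00 to 5.85% of each total, and chi-square per degree of freedom between replicates of a group was 18.2 to 124, so no library repeated another.

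Gene identifiers were matched to GENCODE M21 on GRCm38, which held 20941 of them (99.8%), with identical coordinates for 74.3%. Coordinates are printed as in the deposited table, and exon positions from GENCODE M21. There were 24 symbols turned into dates and 13 symbols held by 2 identifiers, for which the more abundant was used. The reads of genes with many processed pseudogenes were low, with Gapdh at 72.25 and Actg1 at 49.6 against 57425 for Actb, so levels of genes with near-identical copies are uncertain. Of 68 named genes, 15 overlapped another gene in the table, and 10 of the overlapping genes lay on the opposite strand. The most abundant of them outside the mitochondrial genome was Fancl, at 226.375 normalised reads, which overlaps Vrk2. Without known strand use, reads of such pairs cannot be assigned to a single gene.

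The design assumed raw counts and a count model, and the values turned out to be normalised. The test named for that case was used instead, limma 3.58.1 in R 4.3.3 with an intensity trend on log2(value + 1). A gene was kept when at least 4 libraries reached 1 CPM, the value relative to the total of its library, which left 12910 genes and removed 8066. Fold changes are on the log2(value + 1) scale, which understates the change of low genes. P-values were two-sided and adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used for tables and figures. The normalisation of the authors was kept.

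Groups and replicate numbers came from the sample titles. The labels do not say whether equal numbers share a mouse, so the model had no block. The numbers were then checked in the data: deviations from the group means correlated at 0.820 to 0.908 between same-numbered libraries and at -0.597 to 0.477 between others. Same-numbered libraries also shared high Xist (replicates 1 and 4) or Y-linked transcripts (replicates 2 and 3). The numbers were therefore taken to pair the libraries, on the evidence of the values alone, and the paired model, with the replicate number as a block, is given beside a result where it changes a call.

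Tests were checked on simulated libraries drawn with the real totals, with 200 genes changed before the filter and 12910 genes tested after it. Each expected value was the mean of the same-numbered Cre and GFP libraries, so pairing was built in. Noise within pairs came only from counting and an assumed dispersion of 0.01. For simulated Cre against GFP the unpaired model recovered 2.99, 46.2 and 89.1% of genes changed 1.5-, 2- and 4-fold, with 0 false among 89 calls. The paired model recovered 86.6, 100 and 100%, with 10 false among 197 calls. Its higher recovery follows in part from that setup, so it does not measure the power of either model in the real data.

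The named genes were fixed by a rule: Chd4 and Ripk3, the 10 largest increases and 10 largest decreases among genes with an adjusted p under 0.05, a mean of at least 5 CPM and no overlap between the groups, passing over predicted and clone genes, and up to 3 members of each gene list with the smallest p. Of the genes this rule takes, 2 were left out of every count and are not reported here, and some of the others enter only the counts. Other list members are named as examples. The 18 lists, which keep only genes past the filter, were NuRD complex, necroptosis, apoptosis, p53 targets, interferon response, NF-kB and inflammatory genes, muscle stem cell, muscle differentiation, cardiac and slow muscle, cell cycle, imprinted genes, immediate early genes, mitochondrially encoded genes, and markers of fibroblasts, smooth muscle and pericytes, endothelium, macrophages and leukocytes, and Schwann and glial cells. Lists were tested with camera at a preset correlation of 0.01, which compares a list with other genes, again with an estimated correlation, and with fry, which tests whether a list moves one way. List p-values were adjusted over the 18 lists.

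Alternatives were voom on the deposited values and on the recovered reads, median-ratio, upper-quartile and total-count rescaling, no filter and a filter of 5 CPM, other pseudocounts (0.1 and 5), a minimum change of 1 log2 unit, the block, and leaving out each library or pair. The count-model alternatives were replaced by their limma counterparts. Counts of list members called by voom are those without the block. Splicing, exon usage and the paper of the series were not analysed here. No sequence was used.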

Results

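RNA was sequenced from cultured mouse muscle stem cells, the Pax7-expressing satellite cells that rebuild injured muscle fibres. The cells were sorted from mice whose Chd4 gene carries loxP sites, expanded briefly in growth medium with FGF, and infected with adenovirus. One adenovirus carried Cre recombinase, which removes Chd4 exons 12 to 21, and the other carried GFP as the control. Each group held 4 libraries, from 4 mice per group. Whether a Cre and a GFP library of the same number came from 1 mouse is not stated, and the unpaired p-values treat the 8 libraries as independent. Values are read counts per gene that had been scaled between libraries and rounded before deposition. The scaled totals were 28460033, 28876348, 28402534 and 28803479 in Cre libraries 1 to 4, and 28485789, 27897860, 28329374 and 28156032 in GFP libraries 1 to 4. The original depth, estimated from the spacing of the low values, was 29.1, 26.3, 28.2 and 30.4 M reads in the Cre libraries and 25.7, 23.3, 25.3 and 38.0 M reads in the GFP libraries. The mitochondrial share of the total was 1.78% ± 0.528 in Cre and 1.81% ± 0.56 in GFP (SD, n = 4 each).

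The comparison of Cre with GFP asks which transcripts change when Chd4 is lost, and the title of the series points to necroptosis, a regulated form of cell death. Chd4, which encodes the ATPase of the NuRD chromatin remodelling complex, was measured first in every library. It lies on chromosome 6 at 125095981 to 125130591, plus strand, GRCm38 (ENSMUSG00000063870), and the deleted exons 12 to 21 span 125105176 to 125110142. Chd4 stood at 3686, 5480, 5010 and 5134 normalised reads in the Cre libraries and at 17886, 15904, 16634 and 20121 in the GFP libraries. The mean fell from 17636 ± 1848 in GFP to 4828 ± 787 in Cre (SD, n = 4 each), a log2 change of -1.88 ± 0.14 (SE; limma, adjusted p = 0.00328, lower in 4 of 4 pairs). The Cre level was 27.2% of the GFP level (95% confidence interval 21.9 to 33.7%). Between 76.5 and 77.1% of the exonic length of the annotated transcripts lies outside the deleted exons, so reads from the remaining exons still count towards the gene. No Cre library overlapped a GFP library, which matches the group labels.

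Of 12910 genes tested, 108 rose and 32 fell in Cre in the unpaired model, which leaves out the pairing described below (limma, Benjamini-Hochberg adjusted p under 0.05). At an unadjusted p under 0.05 the balance was the other way, with 956 higher and 1201 lower, and groups without overlap were found for 569 genes higher and 797 lower (10.6% of genes). Chance would give 2.86% if all 8 libraries were exchangeable. The pairing described below goes against that, so 2.86% is not the chance rate of this design. The genes that rose after adjustment started from a median GFP value of 95.75, and those that fell from a median of 1026. Changes were ranked among genes that passed this unpaired test, with a mean of at least 5 CPM (scaled reads relative to the library total) and no overlap between groups. The largest increases among them included Ly6a, the stem and progenitor cell antigen Sca-1, which went from 89.8 ± 38.7 to 441 ± 92.1 (log2 change 2.35 ± 0.29, adjusted p = 0.0164). Cacna1h, a T-type calcium channel subunit, rose by 2.34 (adjusted p = 0.0183), and Efna3, an ephrin ligand, rose by 2.25 (adjusted p = 0.00715). Rgs5, a regulator of G-protein signalling that is abundant in pericytes, went from 8646 ± 3475 to 36372 ± 12938 (log2 change 2.08 ± 0.31, adjusted p = 0.0277). The paternally expressed Peg10 went from 5250 ± 847 to 19417 ± 4945 (log2 change 1.87 ± 0.19, adjusted p = 0.00804). Gprasp2, Pak3, Aatk, Zcchc12 and Spn completed the 10 largest increases, with log2 changes of 2.20, 2.14, 1.99, 1.92 and 1.88 and adjusted p-values from 0.0147 to 0.0475.

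The largest decrease was that of Gzmd, from 350 ± 103 to 68.8 ± 22.8 normalised reads (log2 change -2.35 ± 0.28, adjusted p = 0.0147). Gzme, a second granzyme protease encoded beside it on chromosome 14, fell from 1171 ± 205 to 478 ± 112 (log2 change -1.30 ± 0.19, adjusted p = 0.024). Among the genes ranked under the same limits and after Chd4, the formin family gene Fhdc1 fell by 1.49 on the log2 scale (adjusted p = 0.0421). Il18rap, a subunit of the interleukin-18 receptor, fell by 0.89 (adjusted p = 0.0333). Blvra, Chchd6, Arsb and Vrk2 fell by less than 1 log2 unit, with changes of -0.81, -0.81, -0.75 and -0.70 and adjusted p-values from 0.028 to 0.039. Gzmd and Gzme belong to a family of near-identical genes, and Vrk2 overlaps Fancl on the other strand, so the values of these 3 genes are uncertain.

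Same-numbered Cre and GFP libraries deviated together from their group means, with correlations from 0.820 to 0.908. A model with the replicate number as a block called 2861 genes higher and 2804 lower, with the 140 genes of the unpaired model among them. Each of those 140 genes moved one way in 4 of 4 pairs. The paired changes were mostly small, with a median absolute log2 change of 0.33, while 333 genes rose and 44 fell by at least 1 log2 unit. Since the paired model called 5665 of all 12910 genes tested, many calls are due in any list. The paired counts of the NuRD, necroptosis, apoptosis, NF-kB, immediate early and cardiac lists below lay near that share. The unpaired counts fell when any single one of the 8 libraries was left out, to between 11 and 58 called genes. Each such fit has fewer samples and breaks a pair, so the fall cannot show dependence on a particular library. Without some library 22 of the 26 named genes that passed lost their call, 5 of which (Gprasp2, Pak3, Spn, Fhdc1 and Ifih1) also lost it with voom or a filter of 5 CPM, and Chd4, Efna3, Ifit1 and Col1a1 kept theirs in every alternative that tested them.

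**Figure D1:**
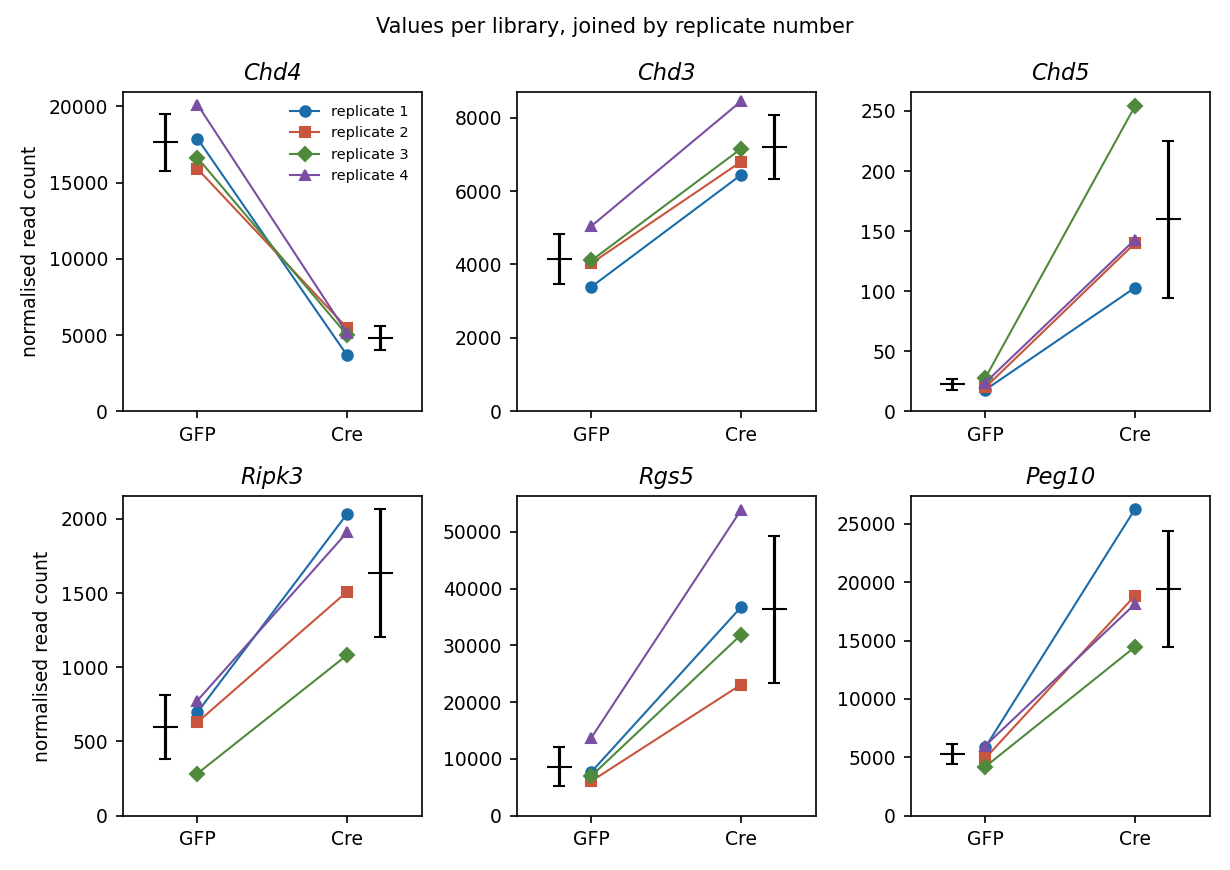
Normalised reads of Chd4, Chd3, Chd5, Ripk3, Rgs5 and Peg10 in each of the 4 Cre and 4 GFP libraries, with lines joining libraries of the same replicate number and the mean ± SD beside them. Chd4 lies lower in every Cre library (mean 4828 against 17636), while the other 5 genes lie higher in Cre in each of the 4 pairs.

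Within the NuRD complex, the paralogues of the deleted ATPase went the other way. Chd3 rose from 4146 ± 681 to 7207 ± 874 (log2 change 0.80 ± 0.13, adjusted p = 0.0352) and Chd5, a paralogue best known from neurons and testis, from 22.5 ± 4.43 to 160 ± 65.3 (log2 change 2.72 ± 0.30, adjusted p = 0.0107). Mta3 rose by 0.38 (adjusted p = 0.0453), a call lost with voom, without a filter, with total-count rescaling (adjusted p up to 0.0743) and when any single library was left out (adjusted p up to 0.156). Of the 15 members tested, 3 rose, Chd4 fell and 11 did not pass the test, with 3 higher and 1 lower also when adjusted over the list alone. In the paired model Gatad2a rose by 0.24 and Gatad2b by 0.17 as well, and Mta1 fell by 0.24, which made 5 higher and 2 lower. The list did not pass the test against other genes (camera, adjusted p = 0.205, paired 0.465).

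Ripk3, the kinase that starts necroptosis by phosphorylating Mlkl, was at 2033, 1509, 1082 and 1909 normalised reads in Cre libraries 1 to 4 and at 697, 630, 284 and 776 in GFP libraries 1 to 4. Its log2 change of 1.51 ± 0.34 did not pass the unpaired test over all genes (limma, adjusted p = 0.0873), although it was higher in 4 of 4 pairs and passed in the paired model (SE 0.10, adjusted p = 3.9e-06). Over the alternatives of the unpaired model, the block included, the adjusted p ranged from 3.9e-06 to 0.217. Mlkl itself differed by 0.06 (adjusted p = 0.914, paired 0.586). Of 19 necroptosis genes tested, 0 passed over all genes, with 4 higher and 2 lower at an unadjusted p under 0.05, and 1 passed when adjusted over the list alone, which was Ripk3. The paired model called 4 higher, namely Ripk3, Birc3 at 0.71, Fas at 0.57 and Ticam1 at 0.48, and 5 lower, including Fadd at -0.35, Ripk1 at -0.27 and Traf2 at -0.27. Fas did not pass without pair 3 (adjusted p = 0.0816), nor Fadd without pair 2 (adjusted p = 0.0531). Voom without the block called 0 members. In the paired model Ripk3, Ticam1 and Traf2 kept their calls in all 13 alternatives, voom included. Rbck1 and Rnf31, also lower, lost theirs in some of them. The paired model called 5665 of all 12910 genes tested and left 10 of the 19 members uncalled. Its count of members alone therefore does not set this list apart. As a list the genes did not pass the test against other genes (camera, adjusted p = 0.848, paired 0.966), with a median change of -0.00 and a mean of 0.10, which differ in sign. Fry, which does not compare a list with other genes, gave an upward adjusted p of 0.963 unpaired and 0.0274 paired. Most lists passed paired fry, so it does not set this list apart. Ripk3 lies on chromosome 14 at 55784996 to 55788857, minus strand.

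Genes of apoptosis showed no call in the unpaired model. Of 18 tested, 0 passed over all genes, 0 when adjusted over the list alone and 0 with voom, and 2 were higher at an unadjusted p under 0.05. With the block, 4 rose, 5 fell and 9 were not called, near the share over all genes (5665 of 12910 called). The proapoptotic Bmf and Bcl2l11 were among those that rose, by 0.99 and 0.58, and Casp2 and the antiapoptotic Bcl2 among those that fell, by -0.49 and -0.43. The list as a whole gave an adjusted p of 0.848 (paired 0.946), with a median of -0.03 and a mean of 0.03, which differ in sign.

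The p53 target list moved upward against other genes (camera, adjusted p = 0.00107, median log2 change 0.19, above 0 in 4 of 4 pairs; adjusted p = 0.209 with an estimated correlation). Without the block none of its 23 members passed over all genes in limma or voom (0 calls), 7 were higher at an unadjusted p under 0.05, and 4 were higher when adjusted over the list alone. The paired model called 13 higher and 1 lower. Examples were Cdkn1a, the cyclin-dependent kinase inhibitor p21, at 26868 ± 2479 in Cre and 19828 ± 2147 in GFP, Trp53inp1 with a log2 change of 0.88 and Perp with 1.11.

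Interferon-stimulated genes rose from low levels. Ifit1, which binds viral RNA, went from 14 ± 3.37 to 158 ± 52 normalised reads (log2 change 3.36 ± 0.30, adjusted p = 0.00597). The RNA sensor genes Ifih1 and Ddx58 rose by 2.48 (adjusted p = 0.0296) and 0.84 (adjusted p = 0.0325), Rsad2 by 1.82 (adjusted p = 0.0175) and Isg15 by 2.03 (adjusted p = 0.0481). Ddx58 lost its call with a filter of 5 CPM (adjusted p = 0.0595) and when any single library was left out (adjusted p up to 0.114). Isg15 lost its call without a filter or with a pseudocount of 0.1 (adjusted p up to 0.0510), and without any single library except GFP 2 (up to 0.147). Leaving out any single library also ended the call of Ifih1, and leaving out some of them that of Rsad2, while Ifit1 kept its call. Of 13 members tested, 5 rose and 8 did not pass, with 8 higher when adjusted over the list alone. The paired model called 9 higher and 1 lower, the latter being Ifit2 with -0.47. The list moved upward (camera, adjusted p = 9.7e-07, median 0.84; adjusted p = 0.0807 with an estimated correlation). Both groups received adenovirus, and no library combined Cre with an intact Chd4 gene.

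Of 11 NF-kB and inflammatory genes, the adhesion molecule Icam1 rose from 11.5 ± 2.38 to 54.3 ± 17.4 (log2 change 2.11, adjusted p = 0.0273) and 10 did not pass. Adjusted over the list alone, 1 was higher and 1 lower, and the paired model called 4 higher and 1 lower, the latter being Nfkb1 with -0.54. Nfkb2, at -0.12, passed in neither model, though it gained a call in 3 of 13 paired alternatives (adjusted p down to 0.0313). The list did not pass the test against other genes (camera, adjusted p = 0.48, paired 0.485).

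By their list medians, cell cycle genes were lower and muscle differentiation genes higher in Cre in all 4 pairs. Of 27 cell cycle genes, 26 fell and 1 rose in the paired model, and in the unpaired model 0 passed over all genes, 15 were lower at an unadjusted p under 0.05, and 8 were lower when adjusted over the list alone. Voom without the block called 0 of them. The proliferation marker Mki67 stood at 5358 ± 2507 in Cre and 10125 ± 3714 in GFP (log2 change -0.998), the S-phase cyclin Ccna2 at -0.96, the replication clamp Pcna at -0.68 and the helicase subunit Mcm4 at -0.59. Ccnd1, a G1 cyclin, rose by 0.18 in the paired model, but did not pass without pair 2 (adjusted p = 0.0557). The list moved downward (camera, median -0.72, adjusted p = 1.1e-09, paired 2.6e-16; adjusted p = 0.402 with an estimated correlation).

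Muscle differentiation genes, chiefly sarcomere proteins and the transcription factors that turn them on, were called only in the paired model, where 29 of 30 rose. Of these, Myod1, Des, Ckm, Neb, Myh1, Actn2, Mybph and Chrna1 lost their calls without some pair (adjusted p up to 0.193). Myod1, Des, Ckm and Mybph also lost theirs under some other alternatives, such as voom with the block or no filter. In the unpaired model 0 passed over all genes, 0 when adjusted over the list alone and 0 with voom, and 1 was higher at an unadjusted p under 0.05. The slow troponin Tnnt1 had a log2 change of 0.70, the giant sarcomere protein Ttn 0.52, the differentiation factor Myog 0.46 and the embryonic acetylcholine receptor subunit Chrng 0.26. The list moved upward (camera, median 0.34, adjusted p = 0.0163, paired 3.3e-09; adjusted p = 0.72 with an estimated correlation). Of 8 cardiac and slow muscle genes, 0 passed in the unpaired model over all genes, over the list alone or at an unadjusted p under 0.05, voom called 0, and 4 rose in the paired model, Tnni3 by 0.96, Csrp3 by 0.26, Tnnt2 by 0.23 and Gata4 by 0.17, Gata4 losing its call in 3 of 13 paired alternatives, without pair 1, 2 or 4 (adjusted p up to 0.1004), and Csrp3 without pair 2 or 4 (adjusted p up to 0.0868). That list gave an adjusted p of 0.46 (paired 0.118).

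Among 18 muscle stem cell genes, 0 passed in the unpaired model over all genes, 0 when adjusted over the list alone and 0 with voom, with 4 at an unadjusted p under 0.05. The paired model called 7 higher and 4 lower. Members of the Notch pathway were among those that rose, Notch3 by 1.00, Hey1 by 0.85, Heyl by 0.83 and Hes1 by 0.46. The surface marker Cd34 at -1.23, the lineage factor Myf5 at -0.57 and Pax7 at -0.14 were among those that fell. Pax7 lost its call with upper-quartile rescaling or no filter (adjusted p up to 0.0576) and without pair 1, 2 or 3 (adjusted p up to 0.172). The list did not pass the test against other genes (camera, adjusted p = 0.46, paired 0.427).

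**Figure D2:**
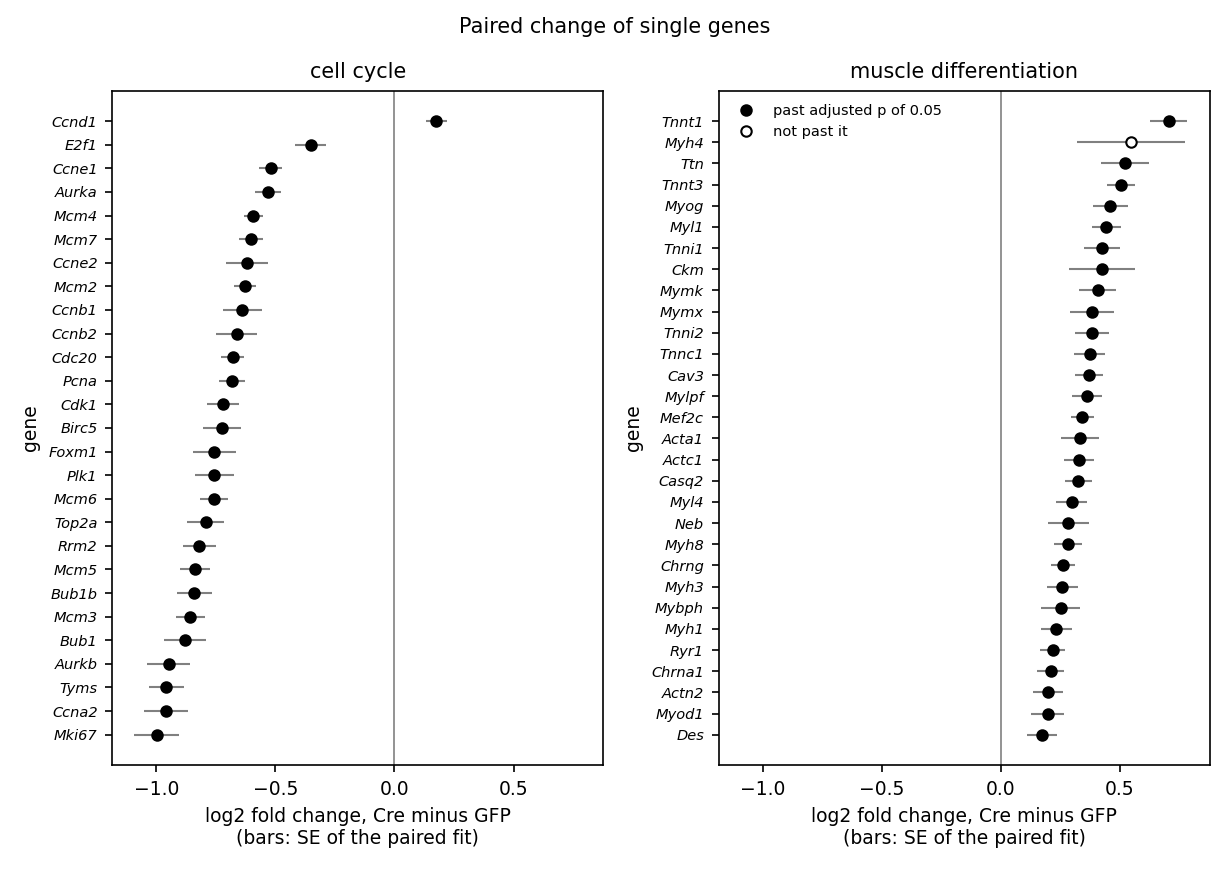
Log2 change from GFP to Cre of the 27 cell cycle and 30 muscle differentiation genes, with bars giving the SE of the paired model. Of the cell cycle genes 26 lie below 0 and Ccnd1 lies above it at 0.18, and all 30 muscle differentiation genes lie above 0.

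Imprinted genes, expressed from a single parental allele, rose as a list (camera, median 0.45, adjusted p = 0.00107; adjusted p = 0.226 with an estimated correlation). Of 16 tested, Peg10 rose over all genes, 4 were higher when adjusted over the list alone, and the paired model called 11 higher and 2 lower. Nnat had a log2 change of 1.66, Dlk1 of 1.14 and the maternally expressed Igf2r of 0.44. Of 14 immediate early genes, 0 passed over all genes, 1 was higher when adjusted over the list alone and at an unadjusted p under 0.05, and voom called 0. The paired model called 5 higher, such as Junb with 0.42 and Zfp36 with 0.47, and 1 lower, the list giving an adjusted p of 0.482 (paired 0.25). Of 7 mitochondrially encoded genes, 0 passed in either model, 0 when adjusted over the list alone, 0 with voom and 0 at an unadjusted p under 0.05 (camera, adjusted p = 0.848, paired 0.946).

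Markers of other cell types that muscle tissue holds also moved. Of 7 fibroblast markers tested, 2 rose, Ly6a and Col1a1, the latter from 12.5 ± 4.36 to 250 ± 95.6 (log2 change 4.19 ± 0.35, adjusted p = 0.00412), with 4 higher when adjusted over the list alone. The paired model called 5 higher, among them Col1a2 at 1.88 and Thy1 at 1.57, and 1 lower, Col3a1 at -0.25. That list moved upward (camera, median 1.57, adjusted p = 0.000249; adjusted p = 0.0807 with an estimated correlation). Dcn, an abundant fibroblast transcript, was below the filter at 5.5 ± 7.72 in Cre and 6.5 ± 10.3 in GFP. Of 7 smooth muscle and pericyte markers, Rgs5 rose, 2 were higher when adjusted over the list alone, and 4 rose in the paired model, of which Cspg4 lost its call without pair 1 or 4 (adjusted p up to 0.115), with Mcam at 3912 ± 1112 in Cre and 1732 ± 598 in GFP (camera, median 0.37, adjusted p = 0.0224; adjusted p = 0.364 with an estimated correlation). Acta2 was at 29084 ± 8750 in Cre and 29166 ± 9102 in GFP. These shifts ran alongside the interferon, p53, imprinted, cell cycle and muscle differentiation changes in the same 4 Cre libraries.

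The remaining marker lists were short, and voom without the block called 0 members of each. Of 4 endothelial genes, 0 passed over all genes, 2 were higher at an unadjusted p under 0.05, when adjusted over the list alone and in the paired model, Tek at 1.46 and Egfl7 at 0.48 (camera, adjusted p = 0.0665, paired 0.079). Of 3 macrophage and leukocyte genes, 0 passed over all genes, 1 was higher when adjusted over the list alone and at an unadjusted p under 0.05, and 2 rose in the paired model, Laptm5 by 1.74 and Cd68 by 1.00 (camera, adjusted p = 0.188, paired 0.079). Of 3 Schwann and glial genes, 0 passed over all genes, 0 when adjusted over the list alone and 0 at an unadjusted p under 0.05, and Ngfr rose by 1.13 in the paired model (camera, adjusted p = 0.848, paired 0.878). The Schwann median was -0.14 and its mean 0.23, which differ in sign. Across the 18 lists, camera passed 7 in either model, and 0 passed with an estimated correlation in either, where 3 lists unpaired and 1 paired had an unadjusted p under 0.05.

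**Figure D3:**
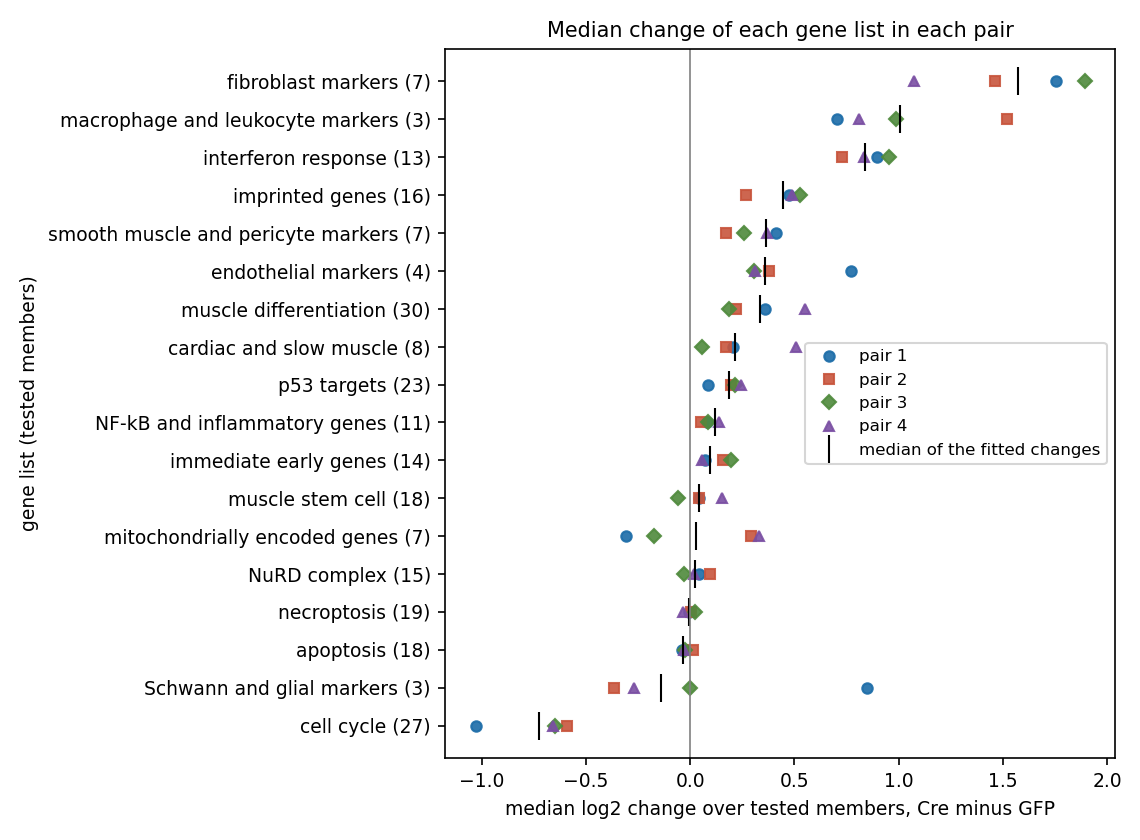
Median log2 change from GFP to Cre of each gene list in each of the 4 pairs of same-numbered libraries, with a black bar at the median of the fitted changes. The cell cycle list lies at -1.03, -0.59, -0.65 and -0.66 and the muscle differentiation list at 0.36, 0.22, 0.19 and 0.55 in pairs 1 to 4.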

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

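Of the tests in this part, those of the list counts over other splits were set before their results were seen, and the rest were chosen only after the result was seen. Single libraries stood apart from the other 3 of their group in 8 of 136 groups of the 68 named genes, by Dixon's ratio at its 95% critical value, where chance alone gives about 6.8. Blvra was 627 in GFP library 3 against 520 to 531 in the others. Traf2 was 640 in Cre library 1 against 778 to 785, Bcl2l11 was 1375 there against 1093 to 1111, and Rsad2 was 316 there against 184 to 193. Ifit1 was 19 in GFP library 2 against 12 to 13. Nfkb1 was 5194 in GFP library 4 against 3888 to 4100 and 3793 in Cre library 4 against 2637 to 2785, and Nfkb2 was 2055 in Cre library 4 against 1882 to 1893.

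Of the 35 ways to split the 8 libraries into groups of 4, 2 gave at least the 140 genes of the real split, so chance could not be excluded from that count alone. The highest other split gave 799 genes and set replicates 1 and 4 against 2 and 3, the division that Xist and the Y-linked genes follow, which points to a structure of the samples. Only 8 splits part every pair, too few for a share under 0.05. In the paired model the real split gave 5665 genes and 1 of the 8 reached that number, the highest of the other 7 giving 0 (limma, with at most 253 genes at an unadjusted p under 0.05, against 6647 in the real split). For the gene lists, 5 of the 35 splits passed at least the 7 of the real split, with 9 in the highest other, so chance could not be excluded there either. Each of the other splits that did so differed from the real split by a single library of each group. They keep much of the real contrast, so this count cannot decide about chance. In the paired model 2 of the 8 splits passed at least 7 lists, with 8 in the highest other, and 8 splits are too few for a share under 0.05. That other split exchanged only the libraries of pair 2, so it too keeps much of the real contrast.

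Chd4 reads remained in every Cre library. If transcripts without exons 12 to 21 were kept at an unchanged level, the value would stay near the 76.5 to 77.1% of exonic length that remains. The measured 27.2% of GFP, with an upper 95% bound of 33.7%, argues against that. Cells that kept an intact gene and a lowered level of a shortened transcript, whose 1536 missing bases keep the reading frame, cannot be told apart, because the table holds no values per exon.

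Markers of other cell types were higher in Cre, among them Col1a1, Ly6a and Rgs5, although these cultures expressed 7 of 16 fibroblast and 7 of 10 pericyte markers past the filter. Of 12 fibroblast markers in the table, 6 were higher in every pair (Gsn by at least 1241 reads, Thy1 by 297, Ly6a by 286, Col1a1 by 135, Col1a2 by 103 and Cd248 by 13). Fibroblasts in the Cre cultures would also bring Dcn, whose mean changed by -1 normalised read with a highest pair gain of 1. That argues against them, though Dcn lies near the floor and 6 other markers rose in every pair. Pdgfra, past the filter, did not, at 122 ± 19.8 in Cre and 119 ± 21.2 in GFP with pair gains from -20 to 38. Clec3b, Postn and Pi16, below the filter, did not rise in every pair either. Col3a1 fell in the paired model, from a mean of 19168 reads in GFP to 16451 in Cre. At that level its own change could hide a fibroblast gain of the size seen for Col1a1, so it cannot decide. Pericytes as the source of the Rgs5 gain of 27726 reads would bring the other 9 members of the smooth muscle and pericyte list, but the median of their highest pair gains was 0.159% of the lowest pair gain of Rgs5, with Pdgfrb gaining 16.5 on average, which argues against them for Rgs5. For members other than Rgs5, pericytes and a change within the cultured cells cannot be told apart, since 4 of the 9 were higher in every pair (Mcam by 2181 reads on average, Abcc9, Cspg4 and Cnn1) and the others, such as Acta2 with -81.5, were not. The flow cytometry sort before culture should have removed both cell types, and the Cre vector itself and the loss of Chd4 cannot be told apart, since 0 libraries held Cre and an intact Chd4 gene, so a change of expression within the muscle stem cells after Chd4 loss stays a hypothesis.

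The medians of the cell cycle list were lower and those of the muscle differentiation list higher in all 4 pairs. A difference in sequencing depth or scaling would follow the depth order of the pairs, but the highest pair median of the cell cycle list was -0.59, and the Cre library held 1.13, 1.13, 1.11 and 0.798 times the reads of its GFP partner in pairs 1 to 4. The muscle differentiation medians were above 0 in those same pairs, which argues against depth. Toxicity of the Cre vector itself and the loss of Chd4 cannot be told apart here, with 0 libraries of Cre and an intact Chd4 gene, and a shift from proliferation towards differentiation may come from either.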

How the results depend on the processing

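The 5-CPM filter, total-count rescaling, voom on recovered reads and the alternatives of the paired model were chosen only after the data were seen, and all other alternatives, the gene lists and the naming rule were fixed before the data were examined. The planned filter of 1 CPM in 4 libraries equals the one used, so it gave no separate value, and the count-model tests were not run on normalised values. Chd4 kept its call in all 18 alternatives of the unpaired model (-1.95 to -1.75) and all 13 of the paired model (-1.99 to -1.75). The 108 genes higher became 58 with the 5-CPM filter, which tests fewer genes, and 10 to 51 when 1 library was left out. The 32 genes lower became 49 with voom on recovered reads, 5 with a minimum of 1 log2 unit, and 1 to 7 when 1 library was left out. Totals without Cre libraries 1 to 4 were 28, 11, 24 and 30, and without GFP libraries 1 to 4 were 49, 42, 28 and 58, of which 28, 11, 24, 30, 46, 42, 27 and 54 were among the 140. With 3 libraries in a group fewer samples remain. Voom on the deposited values called 153 genes, 131 of them shared, and median-ratio, upper-quartile and total-count rescaling called 140, 151 and 152, with 139, 137 and 136 shared. The rescalings set the median log2 change of all genes to -0.00347, 0.0235 and -0.022.

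The replicate block gave 2861 genes higher and 2804 lower, and 333 and 44 of at least 1 log2 unit, because removing differences between pairs shrinks the error. The block left Ripk3 at 1.51 with an adjusted p of 3.9e-06, and its adjusted p over the 13 paired alternatives was 9.1e-07 to 9.2e-05. With it 35 of the 68 named genes gained a call and none of the 26 called lost theirs, and it changed no call of camera at the preset correlation. Camera with an estimated correlation passed 0 lists in both models (3 and 1 at an unadjusted p under 0.05). Fry, which does not compare a list with other genes, passed 5 unpaired and 13 with the block. The latter included the NuRD, necroptosis, NF-kB and immediate early lists, which camera did not pass.

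Directions turned for some genes that had no call in the model concerned. With 1 library left out the ranges were Gata4 -0.0626 to 0.40, mt-Nd5 -0.22 to 0.30, mt-Nd6 -0.27 to 0.23, mt-Nd1 -0.26 to 0.11, Pecam1 -0.0504 to 0.56 and Cd14 -0.46 to 0.0506. The sign turned without Cre library 1 for Gata4, Cre 2 or GFP 4 for mt-Nd5 and mt-Nd6, Cre 3, Cre 4 or GFP 1 for mt-Nd1, GFP 1 for Pecam1 and Cre 4 for Cd14. When a pair was left out of the paired model they were mt-Nd5 -0.0140 to 0.23, mt-Nd6 -0.12 to 0.24, mt-Nd1 -0.16 to 0.0225 and Cd14 -0.39 to 0.0570, turning without pair 4 for mt-Nd5 and mt-Nd6, 1 or 3 for mt-Nd1 and 1 for Cd14. Of 61 named genes called with the block, 5 lost the call without some pair: Foxo3 and Myc without pair 4 (adjusted p 0.0635 and 0.0612), Chrna1 without 2 or 4 (up to 0.0667), Gata4 without 1, 2 or 4 (up to 0.1004) and Cspg4 without 1 or 4 (up to 0.115). Nfkb2 and Mbp, not called with the block, gained a call in 3 and 4 of the 13 paired alternatives. Of 112 other list members called with the block, 29 lost the call without some pair, 14 of them under another alternative too. The cause was not tested. Depth limits genes near the filter of 1 CPM most.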

Other observations

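The genes of the first and second paragraphs were chosen after their values were seen, and of the tests in this part the comparison of neighbouring genes was set before its result was seen. Some genes rose from very low levels. Tubb4a, a tubulin of the nervous system, went from 5 ± 1.41 to 85.3 ± 6.18 normalised reads (limma, log2 change 3.88, adjusted p = 0.00328), Sncg, which encodes gamma-synuclein, from 20 ± 9.06 to 242 ± 115 (log2 change 3.55, adjusted p = 0.024), and Tcfl5, a transcription factor of the testis, from 3.75 ± 4.27 to 104 ± 37.8 (log2 change 4.77, adjusted p = 0.0164). Sncg lost its call without Cre library 1, 2 or 3 or GFP library 1, 2 or 3 (adjusted p up to 0.0836), and Tcfl5 without Cre library 1, 2 or 3 or GFP library 3 (adjusted p up to 0.0761). Arhgap45, known from blood cells, went from 14 ± 6.88 to 186 ± 25.9 (log2 change 3.73, adjusted p = 0.00412). Col7a1, the collagen of anchoring fibrils in skin, went from 471 ± 94.3 to 1673 ± 348 (log2 change 1.82, adjusted p = 0.00804). With the tested genes in 5 equal bins of mean expression, increases of at least 1 log2 unit in the paired model numbered 222, 70, 22, 11 and 8 from the lowest to the highest, and decreases 18, 16, 9, 0 and 1.

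Among genes of at least 50 CPM, 17 rose and 1 fell, Chd4, by at least 1 log2 unit in the paired model. Besides Rgs5 and Peg10 they included the metallothionein Mt1 at 1.83, the lysosomal glycoprotein Gpnmb at 1.80, the axonal motor Kif1a at 1.77, the microtubule protein Map1a at 1.64, Ephx1 at 1.26 and lipoprotein lipase Lpl at 1.07. Of the 17, Ephx1 also passed without the block (adjusted p = 0.0393), as did Sema6b with 1.08 (adjusted p = 0.0147), Maged2 with 1.04 (adjusted p = 0.00804), Gbp9 with 1.012 (adjusted p = 0.0403), Rgs5 and Peg10, while Mt1 (adjusted p = 0.436) and Gpnmb (adjusted p = 0.474) did not. Leaving out any single library ended the call of Ephx1, except GFP 1 (adjusted p up to 0.115), of Gbp9, except GFP 2 (up to 0.137), and of Rgs5, except GFP 4 (up to 0.106). Sema6b lost its call without Cre 2 or GFP 3 (up to 0.0715) and Peg10 without Cre 2 (0.0514). The 44 genes that fell by at least 1 log2 unit in the paired model included some known from DNA replication or repair, Clspn at -1.14, Cdc6 at -1.14, Eme1 at -1.15, Dna2 at -1.08, Exo1 at -1.06, Ung at -1.03 and Fanci at -1.02. Enrichment was not tested.

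Gzmd and Gzme lie next to each other on chromosome 14 and both fell. With the block their neighbour Mcpt8 also fell by 0.58 on the log2 scale, while Ripk3 and Nfatc4, on the same chromosome from 55784996 to 55833943, rose by 1.51 and 1.12. The hypothesis that neighbouring genes changed together was tested along all chromosomes. Of 2589 pairs of neighbouring genes both called in the paired model, 55.7% moved one way, above the 46.9 to 53.5% of 1000 permutations of gene order (permutation p = 0.001, the smallest they can give). Neighbouring genes may therefore share direction slightly more often than chance, and reads shared between overlapping neighbours were not ruled out as a source.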
